A study of Homo sapiens with 12 samples.

How the data were processed

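Gene expression was measured on whole-transcript arrays in Jurkat, an established human line of T cell acute lymphoblastic leukaemia. The 12 arrays held 6 without doxycycline (Dox) and 6 with it, all from 1 clone that carried a Dox-inducible short hairpin RNA against TAL1. Per the labels, array numbers 1 and 4, 2 and 5, and 3 and 6 were technical replicates, so each such pair was averaged and each group had 3 samples. The labels do not say whether the 3 numbered samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. Groups were taken from the labels' treatment field. No array without the hairpin was analysed here, so Dox and the loss of TAL1 came together in every comparison.

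The deposited values are log2 expression values, 1 per probe set and array, made with RMA (background correction, normalization between arrays and a summary per probe set) per the submitters' processing notes. The RMA version, the genome build and the probe set definitions are not given in the sources used here. Array medians lay between 6.61 and 6.73 and single values between 1.47 and 14.3. The column quantiles differed slightly, so the columns do not share 1 distribution. Values are given to 2 decimals and were used as deposited, with no pseudocount, no filter and no new normalization. The number of arrays limits the precision.

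The table held 33297 probe sets. GEO's annotation of the platform paired 19460 with exactly 1 gene symbol and 1754 with several, and 12083 were not listed with a gene. Symbols were updated through the Entrez identifier, which matched for 18389 of the 18417 genes tested. For the 769 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. Limma 3.58.1 in R 4.3.3 (lmFit and eBayes) compared the 3 knockdown with the 3 control samples, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are log2 values, Dox minus no Dox, given with the standard error (SE) of the fit. Intervals are 95% intervals of that fit.

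Gene lists were tested with camera at a preset correlation of 0.01, which asks whether the members of a list shifted relative to the other genes, and p-values were adjusted over the 28 lists. Camera with an estimated correlation, camera on ranks and fry, which asks whether the members of a list move on balance in 1 direction, were run beside it. The version with an estimated correlation started from the expression values, and the preset version from z values of the fit. They therefore differ in more than the correlation. For each list, members were also counted after adjustment over the list alone. The lists, the main test, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named TAL1, then the genes past the threshold whose groups did not overlap (up to 10 in each direction), then up to 4 measured members of each described list with the lowest p, whether or not they passed. All members of the TAL1 complex list could be named, and genes of near-identical families were skipped. Genes named outside the rule are identified as such where they appear.

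The arrays of 1 RNA differed less than the samples of 1 group. The mean variance was 0.0163 between arrays of 1 RNA and 0.0335 between samples of 1 group. Of the 12 arrays, 9 correlated best with their technical partner, and control arrays 1, 4 and 6 with another control array. Whether the shared numbers pair a control with a knockdown sample was checked from the deviations of samples from their group means. Across genes, these correlated at 0.34, 0.40 and 0.39 for numbers 1, 2 and 3, and at most at 0.13 between different numbers. The numbers therefore appear to pair the samples, which rests on the data alone because the labels do not say what a number marks. The main fit had been fixed without the number, so its p-values ignore this pairing. A fit with the number as a replicate block was run for every result.

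The other alternatives were all 12 arrays with the RNA sample as a random block, the first or the second arrays only, all 12 arrays as independent, quantile normalization applied again, centring each array on its median, leaving out probe sets below the 40th percentile of mean level, testing all probe sets, averaging the probe sets of a gene, a trended and robust prior, array quality weights, a fold of at least 1.5, an adjusted p below 0.01, and leaving out each sample in turn. The replicate block with all 12 arrays was added after seeing the data.

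The steps were tested on simulated data for this comparison, with 18417 genes, the spread of the real fit and 200 changed genes in each of 5 runs. The test recovered 23.9% of genes changed by 0.5 log2 units, 89.6% of those changed by 1 and 99.7% of those changed by 2, with a mean of 6.4 false calls per run. A list of 30 genes shifted by 0.25 was called in 5 of 5 runs, and 0 of 135 unshifted lists were called. The simulated genes varied independently, which the genes of a real list do not. The simulation also had no sample pairs and no outlying sample, and its recovery holds for 200 changed genes. In the real fit, TNFAIP3 and CHRNA6 did not pass with differences of 1.99 and 2.03 (limma adjusted p = 0.158 and 0.261). The recovered shares are therefore not the power of the real comparison. Figures were drawn with matplotlib 3.10.9.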

Results

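TAL1, a basic helix-loop-helix transcription factor that is expressed outside its normal setting in many T cell acute lymphoblastic leukaemias, was reduced in Jurkat cells with a Dox-inducible hairpin, and gene expression was compared with cells of the same clone without Dox. The data comprised 3 control and 3 knockdown samples, each measured on 2 arrays whose values were averaged, and 18417 genes. Knockdown sample 2 lay apart from the other 5 samples on the principal component that held 51.7% of the variance, with a score of 35.3 against -13.1 to 4.73. Its root mean square deviation from its group mean was 0.224 log2 units, against 0.103 to 0.155 in the others.

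TAL1 itself was lower with Dox in every sample. Its log2 level was 9.23, 9.34 and 9.36 in the controls and 8.63, 8.93 and 8.91 in the knockdown samples, or 9.31 ± 0.07 against 8.82 ± 0.17 (SD, n = 3 each). The difference was -0.48 ± 0.10 (SE), a decrease of 28.5%, and the differences in the 3 numbered pairs were -0.60, -0.41 and -0.45. TAL1 fell when p-values were adjusted over the TAL1 complex list alone (limma adjusted p = 0.025). It did not pass among all genes (limma adjusted p = 0.367, or 0.164 with the replicate block). The interval of the difference ran from -0.72 to -0.24, so that the largest decrease it allowed was 39.5%, while the labels state a decrease of 80% in TAL1 mRNA for this clone. An exact permutation test of 3 against 3 samples cannot give a two-sided p below 0.1.

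Among the partners of TAL1, GATA3, the T cell transcription factor that binds DNA together with TAL1 in this leukaemia, was higher with Dox. Its level was 9.39 ± 0.38 in the controls and 10.31 ± 0.28 in the knockdown samples, a rise of 0.92 ± 0.21 (limma adjusted p = 0.025 over the list alone, 0.390 over all genes), and all 3 pairs rose, by 1.11, 0.97 and 0.70. With the replicate block its limma adjusted p over all genes was 0.143. Of the 20 measured members of the TAL1 complex list, TAL1 fell, GATA3 rose and the other 18 did not pass the test, counting after adjustment over the list alone. The E-protein genes TCF12 and TCF3, whose products pair with TAL1, had differences of 0.23 ± 0.09 and 0.19 ± 0.10. The core regulators RUNX1 and MYB had differences of -0.03 ± 0.10 and 0.16 ± 0.09, and the bridging factor LMO2, dim on this array at 5.89 in the controls, had 0.02 ± 0.10. The list as a whole was not shifted (median 0.05, camera adjusted p = 0.271).

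The comparison addressed which genes depend on TAL1 in these cells. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm and is itself induced by NF-kB, was the 1 gene of 18417 that changed. It rose from 8.64 ± 0.20 to 10.72 ± 0.21, a difference of 2.08 ± 0.14 (4.22-fold, limma adjusted p = 0.0129), and rose by 2.09, 1.96 and 2.19 in the 3 pairs. TNFAIP3, the A20 enzyme that restrains NF-kB signalling, showed a difference of nearly the same size, from 8.86 ± 0.44 to 10.85 ± 0.31 (1.99 ± 0.24). It did not pass in this test (limma adjusted p = 0.158) and passed with the pairs as a replicate block, as did NFKBIA (limma adjusted p = 0.0041 for both).

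No gene fell. At an unadjusted p below 0.05 there were 780 genes higher and 524 lower with Dox, against 920.9 expected in all by chance. Other splits of the 6 samples into 3 and 3 gave between 103 and 1702 such genes, against 1304 in the real split. Those with more than the real split, at 1330 and 1702, parted only 1 of the numbered pairs. The other splits that part all 3 pairs, as the real one does, gave 138, 662 and 103. The real split was the highest of these 4, which are too few for a share below 0.05. The excess alone therefore cannot be read as an effect of Dox. The balance depended on the fit, with 1132 higher and 1242 lower genes with the replicate block. It also turned in the first arrays alone (643 higher, 680 lower) and without control sample 2 (747 higher, 800 lower). The 3 knockdown values lay entirely above the control values for 1354 genes and entirely below for 1000, together 12.8% of genes, where chance gives 10%. The NFKBIA call was lost when arrays were centred on their medians (adjusted p = 0.0712), when all probe sets were tested (0.0844), and without control sample 2 (0.0516), control sample 3 (0.143) or knockdown sample 3 (0.214). Its difference stayed between 1.96 and 2.19 under these and the other alternatives, and its limma adjusted p lay between 1.03e-09 and 0.214. Use of all 12 arrays with the RNA sample as a random block raised the count of changed genes to 119, of which 101 rose and 18 fell, and leaving out knockdown sample 2 gave 26 higher and 4 lower genes.

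**Figure D1:**
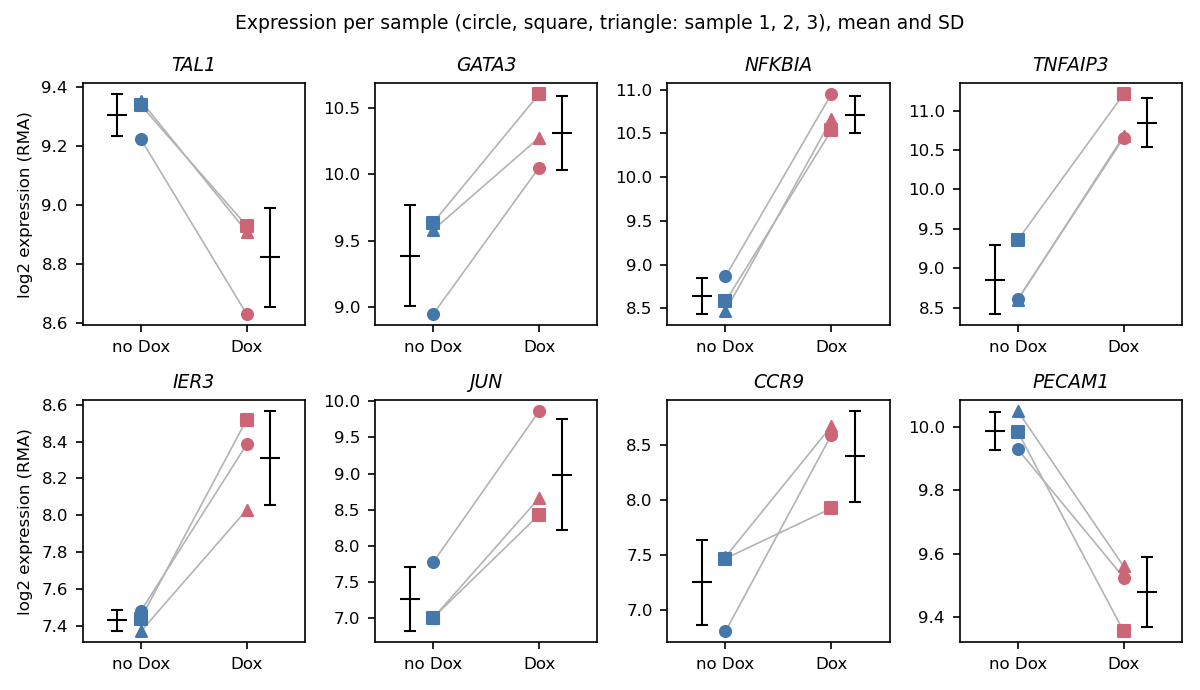
Log2 expression (RMA, vertical axes) of 8 genes in the 3 control (no Dox) and 3 knockdown (Dox) samples, with lines joining samples of the same number and bars giving the mean and SD. TAL1 and PECAM1 were below all controls in the 3 knockdown samples, and GATA3, NFKBIA, TNFAIP3, IER3, JUN and CCR9 were above all controls.

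NF-kB target genes were higher with Dox as a group. Of 24 measured members, 11 rose and 0 fell after adjustment over the list alone, and 13 did not pass, while 1 rose after adjustment over all genes. With the replicate block 12 rose and 1 fell over the list alone. Besides NFKBIA and TNFAIP3 (limma adjusted p = 1.7e-05 and 4.5e-04 over the list alone), IER3, an early response gene that protects against cell death, rose by 0.88 ± 0.13. NFKBIB, which encodes a further inhibitor of NF-kB, rose by 0.63 ± 0.10 (limma adjusted p = 0.0013 and 0.0023 over the list alone). The median difference of the list was 0.25, with 0.44, 0.18 and 0.25 in the 3 pairs, and camera at the preset correlation gave an adjusted p of 2.7e-13. With an estimated correlation, which was 0.059, the call was lost (camera adjusted p = 0.081), while fry called the list (adjusted p = 0.0231).

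Activation and immediate-early genes, which cells switch on within minutes to hours of a stimulus, were also higher. Of 34 measured members, 6 rose and 0 fell after adjustment over the list alone, or 7 and 0 with the replicate block. JUN, a subunit of the AP-1 transcription factor, rose by 1.72 ± 0.38 from 7.26 ± 0.44, its relative JUNB rose by 0.59 ± 0.14, and RGS2, a regulator of G protein signalling, rose by 0.49 ± 0.11 (limma adjusted p = 0.028, 0.0288 and 0.028 over the list alone). The median difference was 0.15 (camera adjusted p = 3.9e-07), and the call was lost with an estimated correlation (adjusted p = 0.548). This list shares 2 members with the NF-kB list.

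Genes known as p53 targets had a median difference of 0.17, and 22 of 28 measured members had positive differences. After adjustment over the list alone 5 rose and 0 fell, or 8 and 0 with the replicate block. TP53INP1, a stress-induced nuclear protein gene, rose by 1.01 ± 0.22. GADD45B, a growth arrest gene that NF-kB also induces, rose by 0.65 ± 0.13, the stress-responsive kinase gene PLK3 rose by 0.41 ± 0.09, and PMAIP1, which encodes the cell death protein NOXA, rose by 0.72 ± 0.19 (limma adjusted p = 0.0248 for each of the first 3 and 0.0309 for PMAIP1, over the list alone). Camera gave an adjusted p of 9.3e-06 at the preset correlation, and adjusted p = 0.081 with an estimated correlation. That estimate was 0.0003, below the preset 0.01, so correlation between the members does not explain the higher p.

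In the apoptosis and BCL2 family list of 34 members, 0 genes passed over the list alone, and 2 rose with the replicate block. The lowest p-values belonged to PMAIP1, to the death receptor genes FAS (0.58 ± 0.15) and TNFRSF10B (0.32 ± 0.10), and to BIRC2 (0.35 ± 0.13), which encodes an inhibitor of cell death. PMAIP1, FAS and TNFRSF10B are also in the p53 list, and BIRC2 is in the NF-kB list. The NF-kB list shares 2 measured members with this one. Without those 2 the median was 0.09 (camera unadjusted p = 0.0059). The whole apoptosis list had a median of 0.09 (camera adjusted p = 0.0306). That call was lost with an estimated correlation (adjusted p = 0.669), with camera on ranks (0.0536), in the first arrays alone (0.0984), with quantile normalization applied again (0.130) or median centring (0.0649), and without control sample 2 (0.108), knockdown sample 1 (0.176) or knockdown sample 3 (0.227). The shift was smaller without these 3 samples, with medians of 0.06, 0.04 and 0.05.

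DNA replication and S phase genes were lower with Dox. Of 40 measured members 37 had negative differences and 20 lay below all controls, with a median of -0.21 and medians of -0.39, -0.17 and -0.10 in the 3 pairs. After adjustment over the list alone 0 members passed, and 3 fell with the replicate block. The members with the lowest p were the replicative helicase genes MCM4 (-0.39 ± 0.11) and CDC45 (-0.36 ± 0.11), the mismatch repair gene MSH6 (-0.36 ± 0.11) and the clamp loader gene RFC2 (-0.30 ± 0.09). Camera called the list at the preset correlation (adjusted p = 2.7e-13) and lost the call with an estimated correlation (adjusted p = 0.548). Mitosis genes had a median of -0.06 and were not called (camera adjusted p = 0.0627). The lowest p there belonged to CCNB1, the cyclin of mitotic entry (-0.45 ± 0.11), and 1 member fell with the replicate block. The list was called as lower without knockdown sample 2 or control sample 1 (camera adjusted p = 5.5e-05 and 3.4e-07), in the first arrays alone (0.0086), with quantile normalization again (0.0191) and with median centring (0.0231). Its median turned positive without knockdown sample 1 (0.04, camera adjusted p = 0.886) and was near 0 without control sample 3 (-0.0021, camera adjusted p = 0.472).

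MYC targets and ribosome biogenesis genes were likewise lower, with negative differences in 39 of 40 members and a median of -0.24 (-0.36, -0.09 and -0.21 in the 3 pairs). Here 0 members passed over the list alone, and 4 fell with the replicate block. PA2G4, a growth-associated nucleolar protein gene, and PAICS, an enzyme gene of purine synthesis, had differences of -0.34 ± 0.12 and -0.30 ± 0.13. Camera gave an adjusted p of 1.8e-05, and the call was lost with an estimated correlation (adjusted p = 0.943). It was also lost without control sample 1 (median -0.10, adjusted p = 0.106) and without knockdown sample 2 (median -0.06, adjusted p = 0.112). The size of the shift depended on the controls, with a median of -0.44 without control sample 2 and -0.15 without control sample 3 (camera adjusted p = 1.6e-17 and 0.0078).

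Genes of the integrated stress response, which the transcription factor ATF4 drives when amino acids run short or proteins misfold, were higher in pairs 1 and 3 but not in pair 2. The median over 37 members was 0.57, -0.12 and 0.51 in the 3 pairs and 0.32 over all samples. SLC3A2, the shared chain of several amino acid transporters, rose by 0.59 ± 0.12 (limma adjusted p = 0.0473 over the list alone) as the 1 member to pass, and 2 members rose with the replicate block. ATF4 itself had a difference of 0.36 ± 0.11, the glutamine transporter gene SLC1A5 had 0.45 ± 0.14, and DDIT4, a stress-induced inhibitor of growth signalling, had 0.67 ± 0.17. Camera called the list at the preset correlation (adjusted p = 2.9e-10) and not with an estimated correlation (adjusted p = 0.748).

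**Figure D2:**
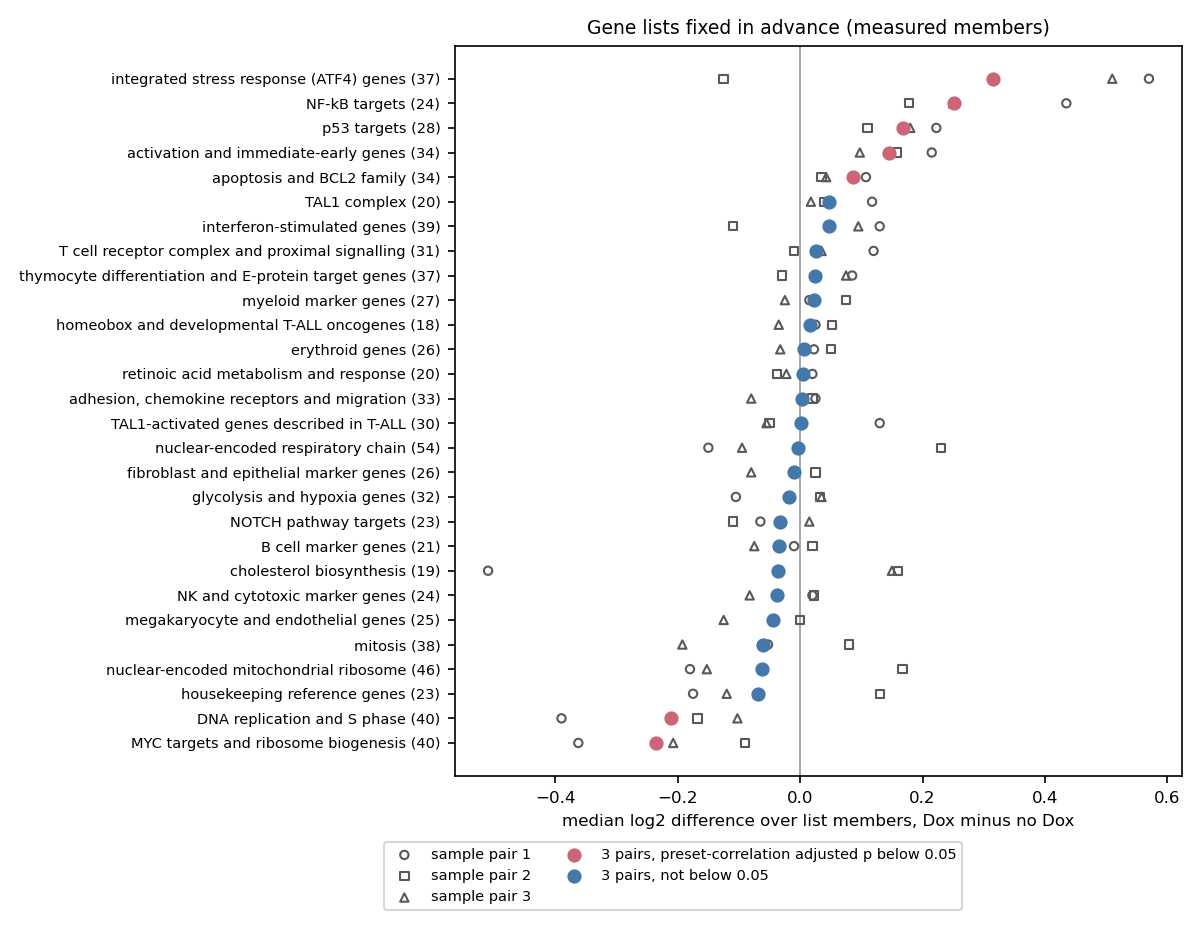
Median log2 difference (Dox minus no Dox, horizontal axis) of the members of each of the 28 gene lists, with filled points for all samples and open symbols for the 3 numbered sample pairs. The 7 lists in red had a camera adjusted p below 0.05 at the preset correlation, and with an estimated correlation 0 lists did.

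Genes described as activated by TAL1 in this leukaemia did not shift. Their 30 measured members split evenly, with 15 positive and 15 negative differences, a median of 0.00 (mean -0.04) and a camera adjusted p of 0.810, and 0 passed over the list alone, against 1 higher and 2 lower with the replicate block. The lowest p in this list belonged to GATA3, also a member, whose difference was positive (0.92 ± 0.21). USP7, a deubiquitinating enzyme gene, had a difference of -0.28 ± 0.08, and the lymphocyte GTPase genes GIMAP7 and GIMAP4 had -0.46 ± 0.17 and -0.42 ± 0.16. ALDH1A2, an enzyme gene of retinoic acid synthesis in that list, had -0.26 ± 0.15, and the retinoic acid list had a median of 0.01 (camera adjusted p = 0.902).

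Thymocyte differentiation genes also showed no shared shift (37 members, median 0.03, camera adjusted p = 0.728). CCR9, the chemokine receptor gene of thymocytes and gut-homing T cells, rose from 7.26 ± 0.39 to 8.40 ± 0.41 (1.14 ± 0.24) when adjusted over the adhesion and migration list (limma adjusted p = 0.0183 over the list alone), but missed the threshold over the thymocyte list (0.0675). SOX4, a transcription factor gene of early T cells, had a difference of 0.48 ± 0.12, ID2, an inhibitor of E-proteins, had 0.57 ± 0.18, and the antigen-presenting molecule gene CD1E had -0.26 ± 0.09. In the adhesion and migration list 5 of 33 members rose and 2 fell over the list alone. They included PECAM1, a junctional adhesion molecule gene of blood vessels and blood cells, which fell by 0.51, and the leukocyte adhesion molecule genes ICAM3 and ICAM2, which rose by 0.38 ± 0.08 and 0.46 ± 0.10. The list moved in both directions (median 0.00, camera adjusted p = 0.852, fry adjusted p = 0.962).

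T cell receptor signalling genes had a median of 0.03 over 31 members (camera adjusted p = 0.582), with the lowest p for THEMIS, a regulator of thymocyte selection (0.37 ± 0.11). The list was called as higher without knockdown sample 2 (camera adjusted p = 0.0148), and its median was -0.0058 without knockdown sample 1 (camera adjusted p = 0.980). NOTCH target genes had a median of -0.03 over 23 members (camera adjusted p = 0.582), where 0 passed over the list alone and 2 rose and 1 fell with the replicate block. SHQ1, a ribonucleoprotein assembly factor gene, had -0.43 ± 0.13, and CDKN1B, the cell cycle inhibitor p27, had 0.48 ± 0.21. Interferon-stimulated genes had a median of 0.05 over 39 members (camera adjusted p = 0.426). IFIT3, an antiviral gene, had a difference of 0.81 ± 0.25, with 1.12, 0.34 and 0.98 in the 3 pairs, and the list was called as higher without knockdown sample 2 or with array quality weights (camera adjusted p = 4.6e-08 and 0.0011). Its median was 0.14 without knockdown sample 2, but -0.01 without knockdown sample 1 and -0.0058 without knockdown sample 3 (camera adjusted p = 0.917 and 0.833).

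In the glycolysis and hypoxia list SLC2A3, a neuronal and leukocyte glucose transporter gene, rose by 0.81 ± 0.16 (limma adjusted p = 0.0341 over the list alone) as the 1 of 32 members to pass, and 2 members rose with the replicate block. The list was not shifted (median -0.02, camera adjusted p = 0.902). The genes of the nuclear-encoded respiratory chain (median 0.00, camera adjusted p = 0.852), the mitochondrial ribosome (-0.06, 0.313) and cholesterol synthesis (-0.04, 0.582) were not shifted either. The respiratory chain list was called as lower without control sample 2, without knockdown sample 2 or with array quality weights (camera adjusted p = 0.0052, 0.0488 and 0.0036), and the mitochondrial ribosome list without control sample 2 or with array quality weights (6.1e-08 and 0.0019). All 3 lists turned direction when certain single samples were left out. The respiratory chain list had positive medians of 0.06 without knockdown sample 1, 0.05 without control sample 3 and 0.02 without control sample 1 (camera adjusted p = 0.0587, 0.272 and 0.887), and the mitochondrial ribosome list 0.02 without control sample 3 (camera adjusted p = 0.717). Cholesterol genes had a median of 0.22 without knockdown sample 1 and -0.26 without knockdown sample 2 (camera adjusted p = 1.5e-04 and 0.0032). In the mitochondrial ribosome list 1 member fell with the replicate block. The homeobox oncogene list had a median of 0.02 (camera adjusted p = 0.810).

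Markers of other cell types did not move with Dox as groups. The median differences were 0.01 for erythroid, -0.05 for megakaryocyte and endothelial, 0.02 for myeloid, -0.03 for B cell, -0.04 for NK and cytotoxic and -0.01 for fibroblast and epithelial markers (camera adjusted p = 0.902, 0.0751, 0.736, 0.476, 0.902 and 0.876). Among them PECAM1 fell (limma adjusted p = 0.0122 over the megakaryocyte and endothelial list alone), and IGLL1, a surrogate light chain gene of precursor B cells, fell by 0.46 (limma adjusted p = 0.043 over the list alone), a call that the replicate block removed. The megakaryocyte and endothelial list was called as lower without control sample 3 or knockdown sample 2, in the second arrays alone and with array quality weights (camera adjusted p = 0.0229, 0.0012, 0.0188 and 0.0139), and its median shrank to -0.0083 without knockdown sample 3 (camera adjusted p = 0.537). Housekeeping reference genes had a median of -0.07 (camera adjusted p = 0.810), with B2M, the light chain of class I antigen-presenting molecules, at 0.38 ± 0.10 and ACTB, the cytoskeletal actin gene, at -0.28 ± 0.10.

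A run of 29 probe sets that follow each other in identifier order, singled out after its values were seen, was lower with Dox throughout. The run held all probe sets with identifiers between those of TMEM203 and PLCXD1, genes of different chromosomes. All 29 differences were negative and 27 lay below all controls, with a median of -1.46 (63.6% lower) and a range from -3.96 to -0.25. The median level was 11.83, 11.78 and 11.85 in the controls and 8.30, 10.36 and 9.78 in the knockdown samples. Of the 20 most negative differences on the whole array 10 lay in this run. The median difference was -2.89, -0.67 and -1.28 in the 3 pairs, and without knockdown sample 1 it was -0.78. At an unadjusted p below 0.05 there were 24, and 0 passed after adjustment over all 33297 probe sets, with or without the replicate block (limma). With all 12 arrays and the RNA sample as a random block, a fit of all probe sets chosen after seeing the data, 14 of the 29 fell (limma). That fit counts arrays of the same RNA towards its degrees of freedom, although each group had 3 samples. The annotation named 4 of the 29, for MPLKIP, MTND2P28, SH3KBP1 and FAF2, and 6 of the 29 had values identical to those of a probe set elsewhere. MTND2P28 is a nuclear copy of a mitochondrial gene. The other probe sets of FAF2 and SH3KBP1, outside the run, had differences of -0.06 ± 0.14 and -0.08 ± 0.11, and those of MPLKIP -2.66 ± 0.51 and 0.08 ± 0.08, so these gene names are uncertain for the run. Over all genes, the run probe sets of MPLKIP, MTND2P28 and FAF2 fell in the 12-array fit and that of SH3KBP1 did not pass (limma adjusted p = 0.0014, 0.0053, 0.0061 and 0.104).

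**Figure D3:**
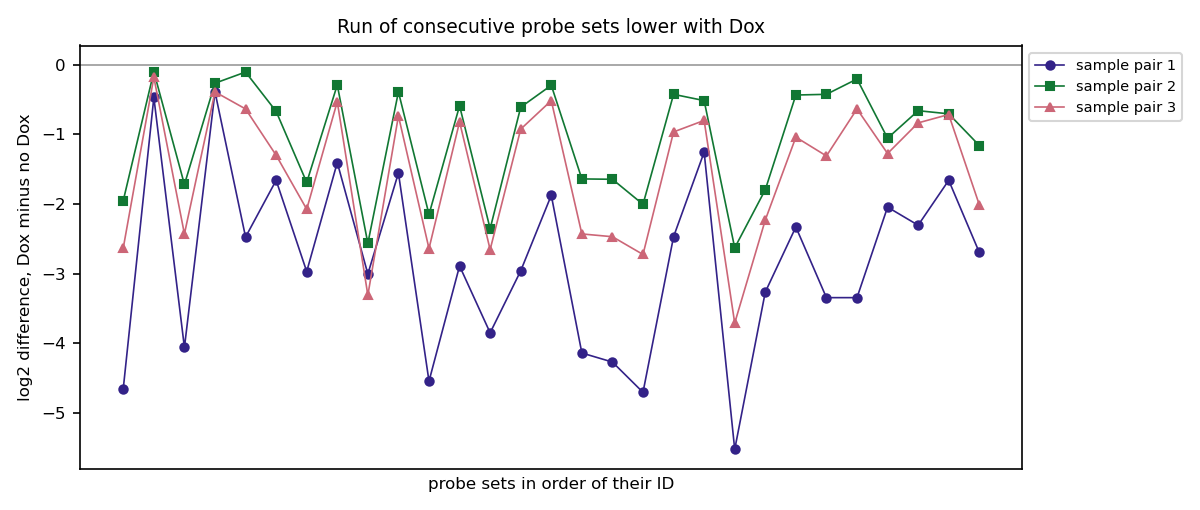
Log2 difference (Dox minus no Dox, vertical axis) of each of 29 probe sets in the order of their identifiers, with 1 line for each numbered sample pair. Every point lies below 0, and the medians of the 3 pairs were -2.89, -0.67 and -1.28.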

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

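TAL1 kept its direction under all 19 alternatives (-0.54 to -0.39) and, tested as a single gene, its side of the threshold. Over all genes it passed with 12 independent arrays (limma adjusted p = 0.0106) and with the replicate block on 12 arrays (0.0038). With the replicate block 2 genes changed, both higher (NFKBIA and TNFAIP3), and its counts of list members stand in the report. All 12 arrays gave 119 changed genes (101 higher, 18 lower) with the RNA sample as a random block, 1223 (615 higher, 608 lower) when the replicate block, added after seeing the data, was combined with it, and 468 (354 higher, 114 lower) when arrays were taken as independent, which ignores the shared RNA. Array quality weights, which gave knockdown sample 2 a weight of 0.27, called 61 genes (56 higher, 5 lower) and 11 lists. Centring on medians, testing all probe sets and an adjusted p below 0.01 each left 0 changed genes (0 higher), and the cause was not tested. Centring also moved the split at an unadjusted p below 0.05 from 780 higher and 524 lower to 1390 and 205, with a median difference of 0.04 over all genes. That split was 1121 and 395 with quantile normalization again, 1132 and 1242 with the replicate block, 1132 and 1265 over all probe sets, 643 and 680 in the first arrays, and 747 and 800 without control sample 2. Leaving out 1 sample gave 0 to 30 changed genes, 0 to 26 higher and 0 to 4 lower, and 6 to 12 called lists. The 30 came without knockdown sample 2, NFKBIA and MPLKIP passed without knockdown sample 1, and ASNS and ASS1, enzyme genes of asparagine and arginine synthesis, passed without control sample 2. Of the 7 called lists camera with an estimated correlation kept 0, camera on ranks kept 6 (apoptosis was lost at adjusted p = 0.0536), and fry called 1 list (NF-kB targets). The estimated correlations of the 7 ran from 0.0003 for p53 targets to 0.74 for MYC targets. Of 83 genes followed, 2 reversed under any alternative. RUNX1 reversed to 0.013 with quantile normalization again, 0.015 with centring and 0.045 with array weights (-0.091 to 0.047 leaving out 1 sample). LMO2 reversed to -0.00175 with array weights (-0.045 to 0.078 leaving out 1 sample). The list of TAL1-activated genes changed the direction of its test at a median of 0.021 with array weights (-0.064 to 0.021 leaving out 1 sample). These values all lay near 0, and the cause was not tested. Of 1556 combinations of gene and alternative, 1378 kept direction and side, 165 newly passed and 5 no longer passed, all 5 for NFKBIA. Signal over background was not used here, so the floor of dim genes such as LMO2 is unknown.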

Other observations

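The gene families, the genes outside the naming rule, and the tests of the named genes in the probe set run, of single samples in that run and of the array's range around TAL1 were chosen only after the results were seen. Genes for ribosomal proteins of the cytosol, the protein part of the translation machinery, had positive differences in 59 of 61 members, and 35 lay above all controls. The median was 0.16, with 0.08, 0.27 and 0.15 in the 3 pairs, and it stayed positive with quantile normalization applied again (0.19) and with median centring (0.20). Camera gave an adjusted p of 2.4e-18 over 5 families at the preset correlation and p = 0.0854 with an estimated correlation, and 0 members passed over all genes (limma, with 18 at an unadjusted p below 0.05). This was opposite in sign to the ribosome biogenesis list. The small nucleolar RNA genes of the SNORD116 cluster, near-identical copies whose probes cannot be counted as independent, had positive differences in 19 of 20 members with a median of 0.38. The neighbouring SNORD115 cluster had 5 of 20 positive and a median of -0.07, but it was dimmer, with a median control level of 2.81 against 5.25 for SNORD116, and whether it was detected at all is unknown. Histone genes had a median of -0.04, although H2BC14 had -0.94 ± 0.10 (limma adjusted p = 0.134).

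Single genes with low p that belonged to no list, picked after their values were seen, did not pass over all genes. TRAF4, an adaptor of tumour necrosis factor family receptors, had a difference of 0.86 ± 0.09, and the ligand genes CD70 and TNFSF9, which costimulate T cells, had 0.76 ± 0.09 and 0.64 ± 0.09 (limma adjusted p = 0.134, 0.158 and 0.165). DUSP10, a phosphatase gene that acts on stress-activated kinases, had 1.27 ± 0.17, and PPP1R15A, which encodes the phosphatase subunit that ends the stress-induced block of translation, had 1.30 ± 0.23 (limma adjusted p = 0.168 and 0.272). All 5 were higher in each of the 3 pairs. They passed with 12 arrays and the RNA sample as a random block, which counts arrays of the same RNA towards its degrees of freedom. With the replicate block, where only NFKBIA and TNFAIP3 passed, they did not (limma). CHRNA6, an acetylcholine receptor gene that is dim in the controls at 5.41, had 2.03 ± 0.35 (limma adjusted p = 0.261). ASS1 had a difference of 1.80 ± 0.42. ASNS, which unlike the genes above belongs to a list, that of the integrated stress response, had 1.47 ± 0.53. The difference of ASNS was 0.06 in pair 2 against 2.14 and 2.22 in the others.

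Of the 10 splits of the 6 samples into 3 and 3, only the real one (1 of 10) gave as many changed genes (1, highest other 0), and 5 of 10 gave as many called lists (7, highest other 13), and 10 splits are too few for a share below 0.05. Among the 4 splits that part all 3 pairs, the fit without the replicate block called 7 lists in the real one and 4, 13 and 5 in the others. With the replicate block, the real one gave 2 changed genes and the others 0. The remaining 6 splits part 1 pair and called up to 10 lists. Camera p-values without the block were compared in the 4 splits that part all 3 pairs. There the real split alone gave so low a p for the NF-kB, immediate-early, p53, apoptosis and MYC lists (1 of 4). For DNA replication and ATF4, 1 other split matched it (2 of 4). Over all 10 splits 4 did so for MYC and 2 for apoptosis, the real one included. A shift of all genes of like expression level is argued against, since 0% of 10000 random lists matched on level had a median as high as that of the NF-kB list, 0% as low as that of the DNA replication list and 0% as low as that of the MYC list. Variation between samples that is unrelated to TAL1, such as in growth state, may account for part of the DNA replication, ATF4 and MYC shifts. The loss of TAL1 and Dox itself both stay open beside it. They cannot be told apart for these or the other called lists, because 0 samples had Dox without the hairpin.

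The decrease of TAL1 (a difference of -0.48, and between -0.54 and -0.39 under the alternatives) was smaller than the one stated for the clone. A limit of the array on any fall at this level is argued against, since 6 of 6363 probe sets with a control mean within 1 log2 unit of TAL1 had a decrease larger than the stated one. Of these 6, 3 lie in the run of 29 probe sets and 3 outside it, 1 of them with values identical to a probe set of the run, and 0 have a gene symbol, so they speak only to the range of the array and not to a named transcript. A compressed response of the TAL1 probe set alone, signal from other transcripts on it, and a weaker knockdown in these samples may each account for the difference, and none of these could be tested with 1 probe set per array.

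For the run of 29 probe sets, a decrease of FAF2 and SH3KBP1 themselves is argued against, since their other probe sets did not follow (-0.06 and -0.08). A decrease decided by 1 knockdown sample is also argued against, since the median closest to 0 with 1 sample left out was -0.78. Whether MPLKIP itself decreased stays open, because its other probe sets split (-2.66 and 0.083). A candidate explanation is a decrease of RNA encoded by the mitochondrial genome. Whether the run's probe sets match that RNA itself or nuclear copies such as MTND2P28 is unknown without the probe sequences. A test was not possible, because 0 named copies lay outside the run. Doxycycline, which inhibits mitochondrial translation, and the loss of TAL1 cannot be told apart here, because 0 samples had Dox without the hairpin.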
